A study of Mus musculus with 43 samples.

How the data were processed

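Gene expression was measured with NanoString panels, which count colour-coded probes bound to single RNA molecules, in 43 samples of mouse kidney grafts. Per the labels' protocols, RNA was isolated with a Qiagen RNeasy mini kit. The deposited values of both tables are on a log2 scale, per the values themselves. In every sample, 2 to the power of the value was a whole multiple of 1 step for all genes, within a tolerance of 0.02, so the authors took log2 of a whole count times 1 factor per sample. How that factor was obtained, the counting software, its version and the treatment of background counts are not given in the sources used here. No genome build is given either, and no coordinates are printed. Control probes were absent from both tables.

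The first table held 689 genes in 37 samples and the second held 681 genes in 6 samples, with 208 genes in both. Gene symbols were matched to the reference gene table of assembly GRCm38.p6, which was used only for names and for which genes neighbour each other. Of the symbols in the first table, 686 matched exactly, 2 through a synonym and 1 not at all. Of those in the second, 11 matched exactly, 658 after a change of letter case, 8 through a synonym and 4 not at all. Total counts per sample, recovered from the steps, ran from 144359 to 750541 in the first table (median 533130) and from 169383 to 926717 in the second (median 691727). These totals limit the precision of genes with low counts.

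The deposited log2 values were used as they are, with no pseudocount, although the design fixed beforehand had allowed for linear values. Genes with a mean below 20 on the linear scale were left out, which left 646 of 689 genes in the first table and 633 of 681 in the second. Samples were grouped by recipient genotype, day and treatment as the labels give them, into 12 groups. Differences were tested with limma 3.58.1 in R 4.3.3. The fit held 1 mean per group over all 37 samples of the first table, or over the 6 of the second, and used eBayes with an intensity trend. Benjamini-Hochberg adjusted p-values under 0.05 were counted as calls, in 13 comparisons. Groups shared 1 estimate of the spread within a table. The labels do not say that replicates are separate animals, so the p-values measure the spread between these samples. They give no batch for the first table.

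Before the data were examined, 27 gene lists, the comparisons, the tests and the alternatives were fixed. The lists with at least 4 tested genes in a table (15 lists in the first and 23 in the second) were tested with limma's fry, whose directional p asks whether the genes of a list move, on balance, one way. These p-values were adjusted over the lists of a comparison. The rule for named genes was also fixed. It took up to 10 genes with the largest rise and up to 10 with the largest fall among the calls, or, where fewer than 6 genes were called, the 6 with the smallest p. It added up to 4 members of each list called by fry, Ccr5 and Ctsg in genotype comparisons, and Cd19, Ms4a1, Cd79a and Cd79b in treatment comparisons. No list was called, so the list members named below, and the values of single samples, were chosen after their values were seen. Single target genes were compared with exact two-sided permutation tests.

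The alternatives were no filter, a minimum mean of 50, a pseudocount of 10, quantile normalization, only the compared groups in the fit, the replicate number as a block, each replicate left out in turn, parts of the untreated day 60 group, and camera with an estimated correlation. Chosen after seeing the data were median scaling, a pseudocount of 1, limma's array weights from REML and gene by gene, the mean of 3 tubular genes as a covariate, a fit of only the compared groups with the block, and an exact test over the signs of differences in numbered pairs. Samples of the same number deviated together from their group means in both CD19 groups (correlation across genes 0.545 to 0.652 for 3 pairs) and in the aCD20 and CD20 groups (0.343 to 0.841 for 3 pairs). Numbers were taken to pair samples there, as a hint from the data, since the labels say nothing about it. In the other comparisons of the first table at least 1 pair had a correlation of 0.1 or less, and the second table was not checked for pairs. None of the 64 pairs of samples within a group was alike to within counting error. Their lowest mean squared difference per gene was 2.26 times counting error, for replicates 2 and 4 of untreated CCR5/CG grafts at day 60. Replicates 2 and 5 of that group had 5.36, and replicates 4 and 5 had 5.09. The same RNA or graft measured in separate runs can differ by more than counting error, so it is not excluded. If replicates 2, 4 and 5 were such a case, comparisons with untreated CCR5/CG grafts at day 60 would count 1 graft more than once. Their n and p-values take all replicates as separate.

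The fits were tested on simulated data with 200 changed genes and the real group sizes, in 20 runs each. Benjamini-Hochberg adjustment is more lenient when many genes change. The shares recovered below hold for that setting and would be lower with few changed genes. Of genes changed 2-fold, 61.4% were recovered in the day 15 comparison, 54.6% in that of the second table, 76.2% in that with B6, 69.9% in that of aCD20, 80.2% in that of late CD19 and 66.7% between the CD19 groups. Of genes changed 4-fold, 91.4%, 90.8%, 97.5%, 96.4%, 98.2% and 94.9% were recovered in the same order. In the aCD20 design, fry called 20 of 20 shifted lists of 8 genes and 2 of 280 unshifted lists. The genes of these lists were drawn at random, while those of most fixed lists vary together between samples. How often fry would call a shift in the fixed lists was not tested, and the share may be lower. Plots were drawn with matplotlib 3.10.9.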

Results

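Kidneys of A/J mice were transplanted into recipients of another strain, and gene expression in the grafts was measured to examine the part neutrophils play in rejection by antibodies. Recipients were B6 mice, mice lacking the chemokine receptor CCR5 (CCR5 KO), or mice with the combined deficiency labelled CCR5/CG KO, whose second part the labels do not spell out. In the first table, untreated CCR5/CG KO recipients were sampled at day 15 (n = 3), day 17 (n = 3), day 35 (n = 3) and day 60 (n = 7). CCR5 KO recipients were sampled at day 15 (n = 3) and B6 recipients at day 60 (n = 4). Treated CCR5/CG KO recipients were all sampled at day 60, in groups labelled aCD20 (n = 3), CD20 (n = 3), early CD19 (n = 3) and late CD19 (n = 5). The fifth late CD19 sample carries no number in its label and was taken as a replicate. CD19 and CD20 are surface proteins of B cells. The labels do not explain how aCD20 differs from CD20. In the second table, 3 samples of CCR5 KO recipients were labelled day 17, and 3 of CCR5/CG KO recipients were labelled days 17, 18 and 19.

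Total counts were lowest in replicate 1 of the day 15 CCR5/CG group (144359), replicate 1 of the CCR5/CG group in the second table (169383) and replicate 1 of the early CD19 group (226541). Other samples held between 321123 and 926717 counts. Of the genes set for a check between genotypes, Ctsg was in neither table and Ccr5 only in the second. Ctsg is 1 reading of CG, which the labels do not give. Ccr5 was 4.48 ± 4.24 (SD, n = 3) on the log2 scale in CCR5/CG and 4.81 ± 0.26 (SD, n = 3) in CCR5 grafts. The exact permutation p was 1.00, and 0.1 is the smallest possible. Both groups of recipients lack CCR5 by label, and the labels name no deficiency of the A/J donors, so Ccr5 checks no label. Its log2 fold change was -0.34 (SE 1.78) with all samples and 2.07 (SE 0.48, limma adjusted p = 0.0880) without CCR5/CG replicate 3. Values are mean log2 values ± SD, and log2 fold changes carry limma's standard error (SE).

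At day 15, Hmox1 and Ero1l were higher in grafts of CCR5/CG KO than of CCR5 KO recipients. Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, was 9.82 ± 1.04 (SD, n = 3) against 8.32 ± 0.27 (SD, n = 3), a 2.83-fold rise (log2 fold change 1.50, SE 0.31, limma adjusted p = 0.0122). Ero1l, which encodes an oxidase for disulfide bonds in the endoplasmic reticulum, was 9.21 ± 0.87 (SD, n = 3) against 7.89 ± 0.10 (SD, n = 3), a 2.51-fold rise (log2 fold change 1.32, SE 0.22, limma adjusted p = 0.000995). For both genes every CCR5/CG sample was above every CCR5 sample. Flt1, a receptor for vascular endothelial growth factor, had a log2 fold change of 1.17 (SE 0.28, adjusted p = 0.0626). Arg1, the arginase of alternatively activated macrophages, had one of 3.67 (SE 0.99, adjusted p = 0.136), the collagenase gene Mmp13 one of 2.54 (SE 0.79, adjusted p = 0.332) and Cox4i2 one of 1.15 (SE 0.38, adjusted p = 0.332). None of these 4 passed the test. Without CCR5/CG replicate 2, Flt1 was at 0.82, Mmp13 at 0.91 and Cox4i2 at 0.75, and without replicate 1 Flt1 (1.54, adjusted p = 0.00165) and Mmp13 (3.72, adjusted p = 0.00497) were called.

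Gene groups at day 15 leaned in different ways, and none passed the list test. All 8 T cell genes had lower means in CCR5/CG grafts (median log2 fold change -0.70, fry adjusted p = 0.302), led by Cd3g (-1.24, SE 0.46) and Cd3d (-1.01, SE 0.35), both components of the T cell receptor complex. Adjusted over the list alone, 2 T cell genes fell (Cd3g and Cd3d), against 0 of the list over all genes tested by limma. The T cell list passed with quantile normalization (adjusted p = 0.0253) but not with median scaling (adjusted p = 0.0746), and all 8 genes kept their direction under both. All 5 tubular injury genes had higher means (median 1.01, fry adjusted p = 0.302), among them Havcr1, the injury marker KIM-1 (1.12, SE 0.75), and Cdkn1a (1.01, SE 0.54). All 6 genes of the type I interferon list also had higher means (median 0.52, adjusted p = 0.302), under both scalings too. In the endothelial list 7 of 9 genes were higher (median 0.36, adjusted p = 0.302), and adjusted over the list alone Flt1 and Nos3 (1.31, SE 0.47) rose. In the chemokine receptor list, adjusted over the list alone, Ccr7 (-1.29, SE 0.46), Cxcr6 (-1.02, SE 0.38) and Cxcr3 (-0.96, SE 0.36) fell while Ccr1 (1.78, SE 0.60) rose. The mean log2 value of the tubular genes Cyp2e1, Lrp2 and Pck1 was 8.88 ± 2.14 (SD, n = 3) in the CCR5/CG and 10.66 ± 0.74 (SD, n = 3) in the CCR5 grafts (difference -1.78, exact permutation p = 0.3). Without CCR5/CG replicate 2 the difference was -0.55.

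Limma thus called 2 of 646 genes higher and 0 lower at day 15, with 61 at an unadjusted p under 0.05 against 32.3 by chance. The groups did not overlap in 147 genes (22.8%), against 10% by chance. The chance values are averages. Many genes vary together between samples, so the counts of a single split can lie far from these averages. Here and below, such counts alone therefore do not show a broad difference between groups. The call of Hmox1 was lost without CCR5/CG replicate 2 (log2 fold change 0.91, adjusted p = 0.216), CCR5 replicate 1 (1.40, adjusted p = 0.138) or CCR5 replicate 3 (1.45, adjusted p = 0.0639), which left 1 call each, and with the replicate block (adjusted p = 0.0629, 1 call). Only the 2 groups in the fit gave 0 calls, with adjusted p = 0.248 for Hmox1 and 0.233 for Ero1l, and leaving out CCR5/CG replicate 1 gave 5.

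**Figure D1:**
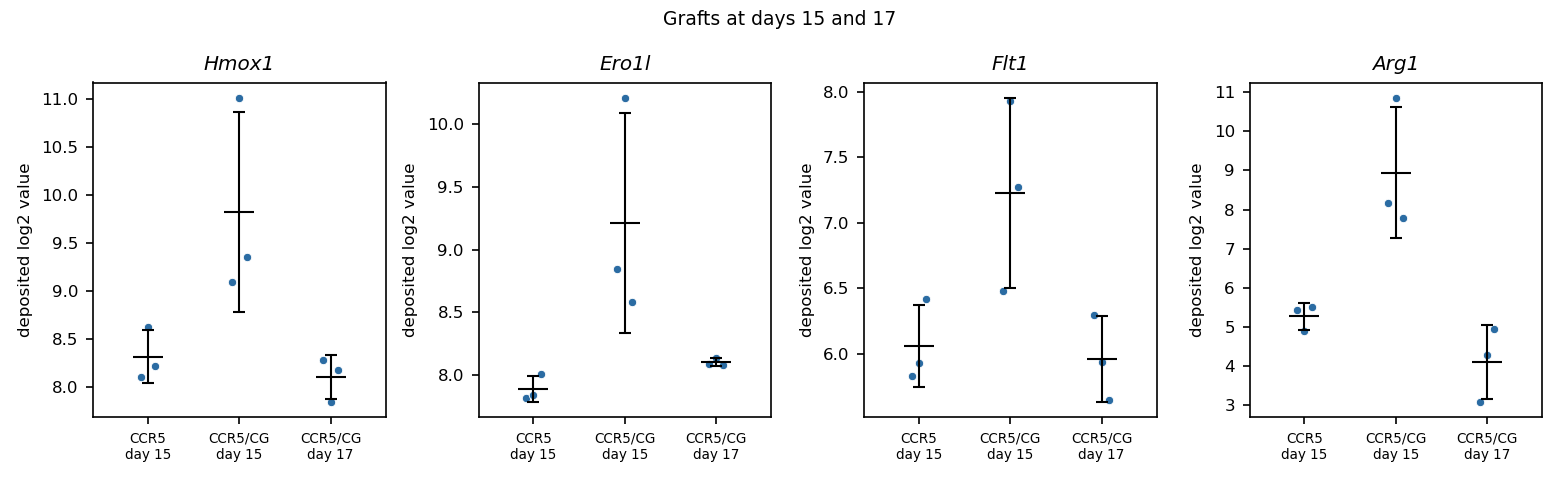
Deposited log2 values of Hmox1, Ero1l, Flt1 and Arg1 in grafts of CCR5 KO recipients at day 15 and of CCR5/CG KO recipients at days 15 and 17 (n = 3 each), with 1 point per sample and the mean and SD as bars. Day 15 CCR5/CG samples of Hmox1 lie at 9.09, 11.01 and 9.36, above all samples of the other groups.

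The second table compared the same genotypes on a panel with more immune genes. Its labels give day 17 for all CCR5 samples and days 17, 18 and 19 for the CCR5/CG samples. Day is thus not separated from genotype in this contrast. The smallest adjusted p was 0.0664, shared by Ccl24, Trem2, Plaur, C3ar1, Ccr1 and Pdcd1lg2, all with higher means in CCR5/CG grafts. Ccl24, an eosinophil-attracting chemokine, was 6.28 ± 0.44 (SD, n = 3) against 3.52 ± 0.65 (SD, n = 3), a log2 fold change of 2.76 (SE 0.44). Trem2, a lipid receptor of macrophages, had a log2 fold change of 1.39 (SE 0.24), Plaur, the urokinase receptor, 1.85 (SE 0.32) and the complement C3a receptor C3ar1 0.91 (SE 0.16). Ccr1, a chemokine receptor of myeloid cells, had 2.12 (SE 0.38) and Pdcd1lg2, which encodes the checkpoint ligand PD-L2, 1.13 (SE 0.21). With a pseudocount of 10, Ccl24 was at 2.01 and Ccr1 at 1.66.

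In the T cell list, 15 of 17 genes of the second table had lower means in CCR5/CG grafts (median -0.64, fry adjusted p = 0.150). Adjusted over the list alone, 6 fell, among them Cd3d (-0.79, SE 0.17), Cd5 (-0.92, SE 0.24) and Cd3g (-1.22, SE 0.38), against 0 over all genes tested by limma. With median scaling the T cell list passed (16 of 17 lower, adjusted p = 0.0172), and with quantile normalization it did not (16 of 17 lower, adjusted p = 0.0673). All 9 neutrophil attractants and inflammatory cytokines had higher means, under both scalings too (median 0.76, adjusted p = 0.150), among them Ppbp (2.27, SE 0.69) and Il6 (1.38, SE 0.47). In the neutrophil list 7 of 8 genes were higher (median 0.89, adjusted p = 0.155), and S100a8, a calprotectin subunit of neutrophils, had 2.12 (SE 0.50). Adjusted over the list alone, S100a8 and Lcn2 (1.33, SE 0.42) rose and Fpr2 (-0.67, SE 0.22) fell. In the macrophage list 13 of 16 genes were higher (11 with median scaling and 10 with quantile normalization), and adjusted over the list alone Trem2, Cd14 (1.12, SE 0.31), Itgam (0.98, SE 0.27) and Csf1r (0.67, SE 0.18) rose. The B cell list was near 0 (median 0.01, adjusted p = 0.759, or -0.17 with median scaling). Asked for changes in either direction, fry gave adjusted p = 0.00260 for the fibrosis and matrix list, where adjusted over the list alone Thbs1 (0.82, SE 0.16) and Vim (0.72, SE 0.16) rose and Thy1 (-0.78, SE 0.21) fell. Camera, which allows for the estimated correlation between genes of a list and asks for 1 direction, called 0 lists here (smallest adjusted p = 0.445) and 0 in the other comparisons (smallest 0.172).

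Limma called 0 of 633 genes in the second table, with 121 at an unadjusted p under 0.05 against 31.7 by chance, and the groups did not overlap in 172 genes (27.2%, against 10% by chance). The median of all genes was 0.18 higher in CCR5/CG grafts, and median scaling removed this shift. Without CCR5/CG replicate 1, limma called 22 genes (20 higher and 2 lower), which included Ccl24, Trem2, Plaur, C3ar1, Ccr1 and Pdcd1lg2, and quantile normalization gave 1 call.

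Across the 194 genes tested in both tables, the log2 fold changes of CCR5/CG over CCR5 grafts had a Pearson correlation of 0.876 and a Spearman correlation of 0.894, and 87.1% had the same sign. Genes are not independent replicates, and the correlation was 0.764 without CCR5/CG replicate 2 of day 15. Sample by sample, with values centred on the mean of the 6 samples of each table, those in the second correlated with the day 15 sample of the same genotype and number at 0.71 to 0.912, and the highest other correlation was 0.497. As deviations from the group means they correlated at 0.724 to 0.894, and the highest other correlation was 0.32. The tables are therefore not treated as separate groups of grafts.

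**Figure D2:**
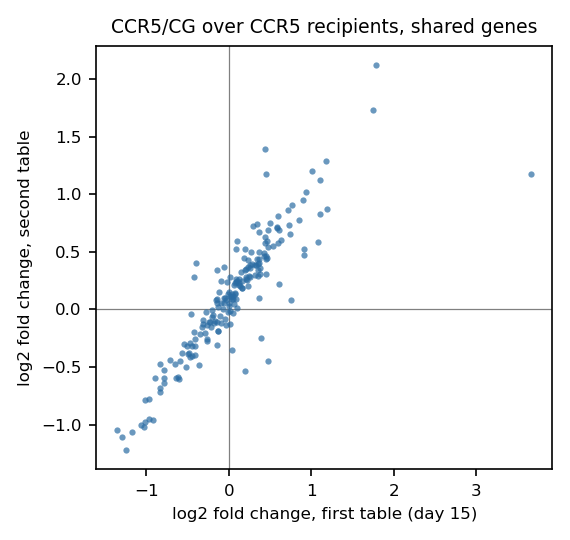
Log2 fold changes of CCR5/CG over CCR5 grafts for the 194 genes tested in both tables, with the first table (day 15) on the x axis and the second on the y axis, 1 point per gene. Of the genes, 87.1% had the same sign in both tables.

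Arg1, Hmox1, Flt1, Ero1l, Daxx and Lamc1 were lower in grafts of CCR5/CG KO recipients labelled day 17 than in those labelled day 15. The day 15 samples matched samples of the second table labelled days 17, 18 and 19 one to one, so their day is in doubt and the contrast is not read as a change over time. Arg1 was 28.8-fold lower at day 17, at 4.10 ± 0.94 (SD, n = 3) against 8.94 ± 1.67 (SD, n = 3), a log2 fold change of -4.85 (SE 0.99, limma adjusted p = 0.00664). Hmox1 was lower by 1.72 on the log2 scale (SE 0.31, adjusted p = 0.00355), Ero1l had a log2 fold change of -1.11 (SE 0.22, adjusted p = 0.00664) and Flt1 one of -1.27 (SE 0.28, adjusted p = 0.0179). Daxx, a transcriptional corepressor, had -0.88 (SE 0.22, adjusted p = 0.0482), and Lamc1, a laminin chain of basement membranes, had -0.76 (SE 0.18, adjusted p = 0.0356). All 5 tubular injury genes had lower means at day 17 (median -1.39, fry adjusted p = 0.0892), and adjusted over the list alone Hmox1 and Cdkn1a (-1.39, SE 0.54) were lower. In the endothelial list 7 of 9 genes were lower (median -0.71, adjusted p = 0.0892), and adjusted over the list alone Flt1, Cdh5 (-0.97, SE 0.31) and Pecam1 (-0.86, SE 0.30) were lower. Adjusted over the list alone, 2 type I interferon genes were lower, Oasl1 (-1.11, SE 0.44) and Isg15 (-0.91, SE 0.35). The tubular genes Cyp2e1, Lrp2 and Pck1 were at 10.97 ± 1.10 (SD, n = 3) at day 17, 2.10 above day 15 (exact permutation p = 0.2), and 0.86 above it without day 15 replicate 2.

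Limma called 6 of 646 genes lower and 0 higher between these days, with 81 at an unadjusted p under 0.05, and the groups did not overlap in 113 genes (17.5%, against 10% by chance). The median of all genes shifted by -0.14, which median scaling removed, and the call of Flt1 was then lost (-1.12, adjusted p = 0.0869). With quantile normalization the calls of Flt1 (-1.01) and Daxx (-0.64) were both lost (adjusted p = 0.234 each). The comparison rests on the day 15 grafts described above and is not independent of them. Without day 15 replicate 2, 0 genes were called (Arg1 -3.89, adjusted p = 0.195, and Hmox1 -1.12 and Ero1l -0.61, adjusted p = 0.0556 each). Without day 15 replicate 1, 35 were called, 3 without day 15 replicate 3 or any one of day 17 replicates 1, 2 and 3, 3 with the replicate block and 0 with only the 2 groups in the fit.

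At day 60, B6 and CCR5/CG KO recipients addressed the contrast named in the study's aim, and no gene passed the test. Ccr1 was 4.43 ± 0.55 (SD, n = 7) in CCR5/CG and 5.98 ± 0.89 (SD, n = 4) in B6 grafts, a log2 fold change of -1.55 (SE 0.46, limma adjusted p = 0.589). Dapk1, a kinase of cell death, had the smallest p (-0.41, SE 0.10, adjusted p = 0.147). The scavenger receptor Marco had 1.35 (SE 0.43), the copper chaperone Atox1 -0.30 (SE 0.09), the basement membrane gene Nid2 -0.36 (SE 0.15) and the junction gene F11r -0.34 (SE 0.14). No gene list moved in a way that passed the test (smallest fry adjusted p = 0.999). Limma called 0 of 646 genes, with 15 at an unadjusted p under 0.05 against 32.3 by chance. With the mean of the 3 tubular genes as a covariate, Ccr1 was the 1 gene called (-1.49, SE 0.26, adjusted p = 0.00244).

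Over later times in untreated CCR5/CG KO recipients, no gene or list passed the test. From day 17 to day 35, Fpr1, a receptor for bacterial peptides on myeloid cells, had a log2 fold change of 1.00 (SE 0.41), the death ligand Tnfsf10 -0.94 (SE 0.38), Phykpl 0.60 (SE 0.22), the laminin gene Lama3 0.51 (SE 0.21), F8 0.51 (SE 0.21) and the cytokine receptor subunit Il6st 0.38 (SE 0.15). From day 35 to day 60, Nr1h3, a nuclear receptor for oxysterols, had -0.61 (SE 0.15, limma adjusted p = 0.239), and Phykpl -0.48, Lama3 -0.46, F11r -0.42, Hikeshi -0.38 and Phlpp1 -0.34 followed. Without day 35 replicate 2, Phykpl was at 0.37 and Lama3 at 0.30 from day 17 to day 35, and Phykpl at -0.25, Lama3 at -0.25 and F11r at -0.26 from day 35 to day 60. From day 17 to day 60, Spib, a transcription factor of B cells, had 1.51 (SE 0.43, adjusted p = 0.885) and the collagen gene Col6a3 -0.82 (SE 0.25, adjusted p = 0.911). Angptl4 had 1.20 (SE 0.42), the fibrinogen gene Fgg 0.97 (SE 0.38), F8 0.53 (SE 0.18) and Nr1h3 -0.40 (SE 0.15). Limma called 0 genes in each of the 3 comparisons, with 20, 25 and 19 at an unadjusted p under 0.05.

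The B cell genes of grafts from treated recipients at day 60 were compared with those of untreated CCR5/CG KO recipients (n = 7). Ms4a1, which encodes CD20, was 4.65 ± 0.62 (SD, n = 3) in the CD20 group and 6.16 ± 0.87 (SD, n = 7) in untreated grafts, a difference of -1.51 (exact permutation p = 0.025, adjusted p = 0.325 over 13 such tests). In the aCD20 group Ms4a1 was 6.20 ± 1.16 (SD, n = 3), a difference of 0.04 (exact p = 0.967). It was 5.45 ± 0.90 (SD, n = 3) in the early and 5.69 ± 0.90 (SD, n = 5) in the late CD19 group, differences of -0.71 and -0.48 (exact p = 0.283 and 0.352). Cd19 differed from untreated grafts by -0.14 with aCD20, -0.71 with CD20, -0.31 with early and -0.13 with late CD19 (exact p = 0.858, 0.3, 0.542 and 0.828). Among untreated grafts, Ms4a1 was highest in replicates 2, 4 and 5 (7.06, 6.91 and 7.18), against 4.97 to 5.71 in the others. Cd19 was also highest in these replicates, which were the most alike of the group and may not be separate grafts. Counted once, they would lower the untreated means of both genes and bring the differences with CD20 nearer to none. A test with them counted once was not run. Cd79a was in neither table and Cd79b only in the second, which holds no treated graft. The B cell list had 3 tested genes in the first table, Cd19, Ms4a1 and Spib, and was not tested as a list.

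**Figure D3:**
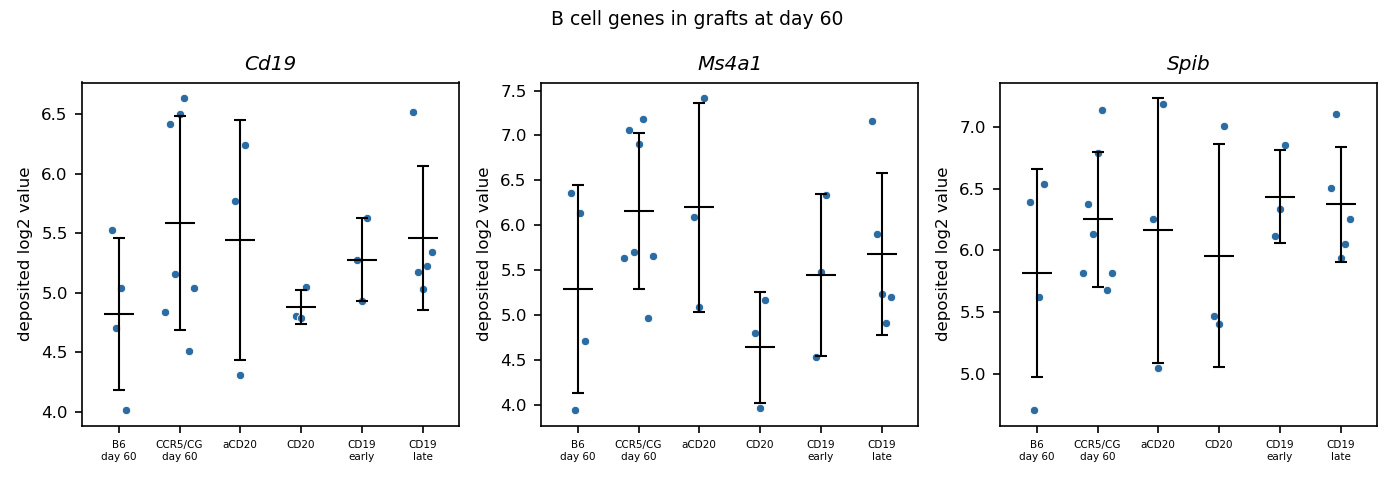
Deposited log2 values of Cd19, Ms4a1 and Spib in day 60 grafts, with 1 point per sample and the mean and SD as bars. CD20-treated grafts had the lowest mean of Ms4a1 (4.65), and the SDs of the treated groups overlap that of untreated CCR5/CG grafts for Cd19 and Spib.

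With aCD20, all 8 interferon gamma inducible genes had lower means than in untreated grafts (median -0.59, fry adjusted p = 0.501), and they did so under both scalings. Most lists leaned the same way: all 12 MHC genes, all 8 cytotoxic, all 7 NK cell, all 6 inflammasome and all 5 tubular injury genes also had lower means. Among the interferon gamma inducible genes the chemokine gene Cxcl11 had -0.84 (SE 0.32), the guanylate-binding protein gene Gbp3 -0.68 (SE 0.26) and the immunoproteasome gene Psmb8 -0.40 (SE 0.17). Much of this rested on aCD20 replicate 2, the sample with a first component score of 21.9: without it 7 of the 8 genes were lower with a median of -0.20, and Cxcl11, Gbp3 and Psmb8 were at -0.48, -0.39 and -0.15. Marco had -1.28 (SE 0.47), the Wnt pathway gene Tcf7l2 -0.52 (SE 0.18) and Snai2 0.53 (SE 0.23). With CD20, Marco had -1.69 (SE 0.47, limma adjusted p = 0.748), Flt1 0.60 (SE 0.24), Itpr2 0.46 (SE 0.19), the interferon-induced gene Ifi27 0.44 (SE 0.16) and the ubiquitin ligase gene Cul1 -0.32 (SE 0.10). Without CD20 replicate 2, Ifi27 was at 0.17 and Itpr2 at 0.25. With a pseudocount of 10, Marco was at -1.13 with CD20. Limma called 0 genes with aCD20 and 0 with CD20, with 12 and 11 at an unadjusted p under 0.05.

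With early CD19, Ppard, a nuclear receptor for fatty acids, had a log2 fold change of 0.91 (SE 0.25, limma adjusted p = 0.648), the heat shock protein gene Hsp90aa1 0.71 (SE 0.24) and Hikeshi 0.46 (SE 0.14). The tight junction gene Ocln had -0.55 (SE 0.20), Il1rap -0.51 (SE 0.19) and the antigen presentation gene H2-DMb1 -0.30 (SE 0.11). With late CD19, the Wnt receptor Fzd2 had 0.72 (SE 0.20), the fibrinogen gene Fga -1.24 (SE 0.36) and Il6st 0.36 (SE 0.11), each with limma adjusted p = 0.481. Ppard had 0.61 (SE 0.21), Rps6ka2 0.53 (SE 0.19) and Spop 0.28 (SE 0.10). With median scaling Il6st was at 0.26 and Spop at 0.17, and with quantile normalization Spop was at 0.16. All 17 fibrosis and matrix genes had higher means with late CD19, under both scalings too (median 0.34, fry adjusted p = 0.838). The tubular genes Cyp2e1, Lrp2 and Pck1 were at 9.97 ± 1.64 (SD, n = 5) there and at 11.38 ± 0.48 (SD, n = 7) in untreated grafts (difference -1.42, exact permutation p = 0.0492, unadjusted and 1 of 12 such tests), and the difference was -0.96 without late CD19 replicate 1. Limma called 0 genes with early and 0 with late CD19, with 15 and 36 at an unadjusted p under 0.05. It called 1 gene, Hsp90aa1 (adjusted p = 0.0431), without early CD19 replicate 1 (the log2 fold change was 0.39 without replicate 3), and 3, among them Fzd2 and Fga (adjusted p = 0.0437 each), without late CD19 replicate 3.

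Between the CD19 groups, all 17 fibrosis and matrix genes had lower means with early than with late treatment (median -0.65, fry adjusted p = 0.681), and 16 did so under both scalings. All 9 complement, 8 T cell, 7 NK cell, 6 chemokine receptor and 4 plasma cell genes also had lower means, and the mean of the 3 tubular genes was 1.31 higher with early treatment (exact permutation p = 0.321), or 2.63, 0.63 and 0.67 higher without early CD19 replicates 1, 2 and 3, and 0.85 without late CD19 replicate 1. In the 3 pairs of the same number the tubular mean was higher with early treatment in each. It was 8.64 against 8.11, 12.63 against 11.31 and 12.56 against 11.92, and no paired test of it was run. Without early CD19 replicate 3 the median of the fibrosis and matrix list was -0.37, and without replicate 2 it was -0.42. The median of all genes was -0.16. Il1rap had -0.69 (SE 0.20, limma adjusted p = 0.788), the T cell chemokine receptor Cxcr3 -0.95 (SE 0.32), Col6a3 -0.77 (SE 0.27), Fzd2 -0.75 (SE 0.25), Maml3 -0.65 (SE 0.22) and Hsp90aa1 0.75 (SE 0.25). With quantile normalization Il1rap and Fzd2 were at -0.45 and Maml3 at -0.41. Between aCD20 and CD20, all 8 interferon gamma inducible genes had lower means with aCD20 (median -0.66, fry adjusted p = 0.484). Without aCD20 replicate 2, 6 did (median -0.36), and without CD20 replicate 3 the median was -0.41. Adjusted over the list alone, 3 of them fell, Cxcl11, Cxcl10 (-0.99, SE 0.36) and Stat1 (-0.67, SE 0.26), against 0 over all genes tested by limma. Csnk1d had -1.09 (SE 0.35), Kmt2d -0.78 (SE 0.28), the complement-related gene Cfhr2 1.29 (SE 0.48), Cul1 0.40 (SE 0.12) and Csnk1a1 0.38 (SE 0.14). Ms4a1 was 1.55 higher with aCD20 than with CD20 (exact permutation p = 0.2, where 0.1 is the smallest possible). In the 3 pairs of the same number it was higher with aCD20 in each, by 1.13 to 2.25 (SD 0.61, exact permutation p = 0.25 over the signs of the pairs, the smallest possible, a test chosen after the data were seen). Limma called 0 genes between the CD19 groups and 0 between aCD20 and CD20, with 35 and 31 at an unadjusted p under 0.05. Without early CD19 replicate 1 it called 1 gene between the CD19 groups, Hsp90aa1 (adjusted p = 0.0478), whose log2 fold change was 0.43 without replicate 3.

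The 4 treatments were compared with the same untreated grafts, which alone makes their fold changes alike. The correlation across genes was 0.541 between CD20 and late CD19, 0.410 between CD20 and early CD19, 0.241 between aCD20 and early CD19 and 0.231 between the CD19 groups. It was -0.0657 between aCD20 and CD20 and -0.125 between aCD20 and late CD19. Simulated unchanged groups gave medians of 0.318 to 0.397. Their 95% ranges held every observed value but were wide, for instance -0.697 to 0.916 for CD20 and early CD19. Almost any correlation would lie within them, so they decide nothing. The covariance of CD20 and late CD19 was 0.0536 against a simulated 0.0347, and 0.0355 with the untreated grafts split between both. The other 5 covariances (-0.0107 to 0.0287) lay below their simulated values (0.0335 to 0.0384). The simulated controls were drawn from the pooled spread of all these groups, treated ones included. The untreated group was tighter, with an SD of the tubular mean of 0.48 against 1.50 to 2.29 in the treated groups. The simulated covariances can thus be too high, and no conclusion is drawn from them.

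The largest spread in the first table lay within groups, where tubular genes moved one way and immune and matrix genes the other. The first principal component of all 646 genes held 47% of the variance, of which 15.8% lay between groups. The third held 9.1%, of which 66.8% lay between groups. Its scores were negative in all samples labelled day 15 or 17, and in some later ones. The lowest was that of day 15 CCR5/CG replicate 2 (-16.7). Within groups, a component computed without Cyp2e1, Lrp2 and Pck1 (54.5% of the variance within groups) correlated with the mean of these 3 genes, which mark differentiated tubules, at a Pearson correlation of 0.877 and a Spearman correlation of 0.896 (n = 37, permutation p = 1e-05 for both, the smallest possible, adjusted p = 2e-05 over 2 relations). Without the 2 samples farthest from the median of the tubular mean, Pearson's correlation was 0.89. The mean of the macrophage list correlated with the component, computed without the genes of the list, at a Pearson correlation of -0.945 and a Spearman correlation of -0.911 (n = 37, permutation p = 1e-05 for both, the smallest possible, adjusted p = 1.25e-05 and 1.5e-05 over 15 lists), and at -0.926 without the 2 samples farthest from the median of the list mean. The endothelial list had the weakest relation (Pearson -0.264, Spearman -0.229, permutation p = 0.115 and 0.172, also after adjustment, and -0.238 without the 2 farthest samples). The Pearson correlations of the other lists ran from -0.961 (inflammasome) to -0.527 (plasma cell), each with an adjusted permutation p of 0.00107 or less. Other genes that vary together with the 3 tubular genes, or with a list, stay in the component. These correlations thus describe shared variation, and their p-values are no independent test.

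**Figure D4:**
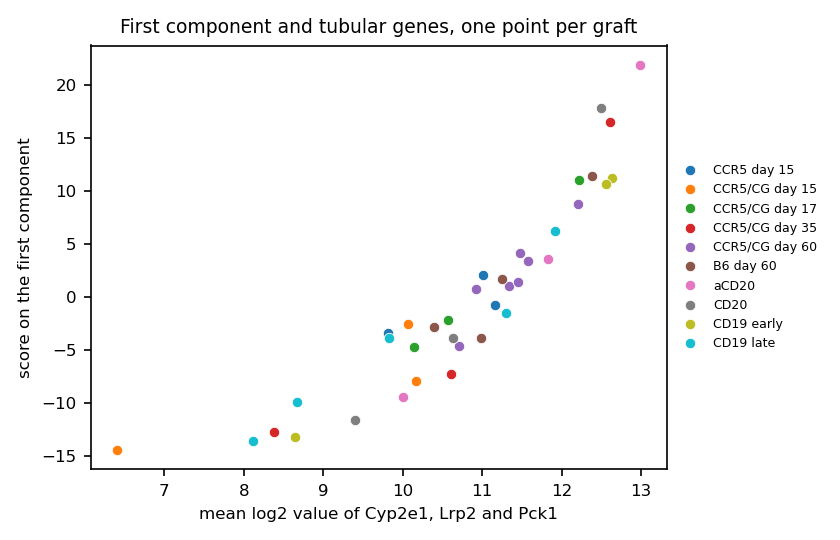
Score of each of the 37 samples of the first table on the first principal component (y axis) against the mean log2 value of Cyp2e1, Lrp2 and Pck1 (x axis), coloured by group. Scores rise with the tubular mean, and the component holds 47% of the variance.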

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

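The tests of explanations in this part were chosen only after the results were seen.

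In 8 of 62 checks within a group of 4 to 7 samples, the highest or lowest sample stood far from the others, against 3.1 that chance gives. The checks covered named genes, the total count and the first component score, and all 8 were of named genes. In untreated CCR5/CG grafts at day 60, replicate 6 was low for Col6a3 (6.74, median of the others 7.48) and Cxcl11 (5.02, median 6.10) and high for Lama3 (7.77, median 7.40). Replicate 4 of that group was high for H2-DMb1 (11.63, median 11.43), replicate 1 for Hsp90aa1 (11.92, median 11.12), and replicate 2 was low for Ppard (5.35, median 5.97). Among B6 grafts, replicate 1 was low for Atox1 (9.65, median 9.78). With late CD19, replicate 1 was high for the B cell gene Cd19 (6.52, median 5.20).

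Hmox1 and Ero1l were higher in day 15 CCR5/CG than CCR5 grafts. CCR5/CG replicate 2 had the highest values. Without it both fold changes stayed at least 3.6 SE from 0. Ero1l at 0.83 (SE 0.14, before 1.32, SE 0.22) stayed past the threshold. Hmox1 at 0.91 (SE 0.25, before 1.50, SE 0.31) lost its call (limma adjusted p = 0.216) because its fold change shrank more than its SE. Both genes were picked for their small p in these same samples, and the SE draws on the spread of all groups. With only the 2 groups in the fit the SE was 0.41 for Ero1l (limma adjusted p = 0.233) and 0.49 for Hmox1 (adjusted p = 0.248). Replicate 2 as the whole cause is therefore not excluded. The shallow replicate 1 is argued against by the higher fold changes without it (mean 1.69, Hmox1 1.87 and Ero1l 1.51). With the tubular mean as a covariate, the larger limma adjusted p of both genes was 0.0212 (Hmox1 1.31, SE 0.30, and Ero1l 1.14, SE 0.20). This fit also drew on the spread of all groups. Replicate 2 had a tubular mean of 6.41, and all other samples had 8.11 or more, so its adjustment is an extrapolation. A lower share of tubular tissue as the whole cause is therefore not excluded. A hypoxia response of these grafts stays open, since a list of 7 other hypoxia-induced genes had a fry adjusted p of 0.165 at day 15. The genotype also stays open. So does the day, since these CCR5/CG samples matched samples of the second table labelled days 17, 18 and 19, and the CCR5 samples matched ones labelled day 17. The 3 samples against 3 make 10 splits, too few for a share under 0.05 (2 genes for the real split, 1 of 10 with as many, and 0 for the highest other).

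The day 15 grafts of the first table and the samples of the second resembled each other one to one. A candidate explanation is that the same 6 RNA samples were measured on both panels, although the labels give other days. The mean correlation within groups was 0.799 for the best of 36 assignments and 0.514 for the next, all 6 best partners had the same number, and the total counts had a rank correlation of 0.943. Likeness of grafts of the same genotype is argued against by values centred on the mean of the 6 samples of each table. Partners then correlated at 0.71 to 0.912, and the highest other correlation was 0.497. Within groups each sample had a correlation of at least 0.724 with its best partner, against at most -0.102 with the others of its genotype. Centring 3 samples on their own mean forces much of this last contrast, so it is not counted as evidence.

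The first component of the first table separated samples within groups. Library depth is argued against, with a Pearson correlation of 0.0606 within groups (n = 37, permutation p = 0.721). A different share of tubular tissue in the pieces taken is argued against as the whole cause: it would raise the genes of all other cells alike, but per log2 unit of the tubular mean the macrophage list moved by -0.291 (SE 0.0458) and the endothelial list by -0.0574 (SE 0.0308), a difference of slopes of -0.234 (SE 0.0498). A varying share of infiltrating immune cells is argued against as the whole cause too: it would dilute endothelial and tubular genes alike, a slope near 1, but the slope of the endothelial list was the -0.0574 given above (95% interval -0.121 to 0.00592). That slope averages genes that went both ways. Their weights in the first component ran from -0.065 (Vcam1, also a tubular injury gene here) to 0.045 (Kdr). All lay below those of Lrp2 (0.107), Pck1 (0.131) and Cyp2e1 (0.195). Infiltration together with a loss of tubular expression, from injury for instance, stays open, and no biological explanation from the design was tested.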

How the results depend on the processing

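Array weights, the tubular covariate, median scaling, the pseudocount of 1, the fits of only the compared groups with the block and the test of single genes in numbered pairs were tests chosen only after the data were seen. For the changes below the cause was not tested, except where samples or genes were left out of a fit by construction.

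Housekeeping scaling was not run, since the tables hold 1 and 2 housekeeping genes of the fixed list, and a count test was not run because the values are not raw counts. No called gene changed sign under any alternative that was run. Of 1837 values of named genes under the alternatives, 25 changed sign, all of them uncalled and all of Ccr5, Cd19 or Ms4a1. Ccr5 in the second table went from -0.34 to 2.07 without CCR5/CG replicate 3. With aCD20, Cd19 went from -0.14 to 0.42 without aCD20 replicate 2, and Ms4a1 from 0.04 to -0.59 with array weights and to -0.57 without aCD20 replicate 3. For CCR5/CG against CCR5 grafts at day 15, the 2 called genes became 4 with a pseudocount of 10, 0 with only the 2 groups in the fit, 1 with the replicate block, 6 with the tubular covariate and 1 to 5 without single replicates. The lists called there went from 0 to 1 with quantile normalization (T cell), 1 with only the 2 groups, 1 with the tubular covariate and 0 to 2 without single replicates. In the second table the count of 0 became 1 with quantile normalization and 0 to 22 without single replicates, and the lists 1 with median scaling and 0 to 1 without single replicates. Between days 15 and 17, the 6 calls became 0 with only the 2 groups, 3 with the replicate block, 3 with the tubular covariate and 0 to 35 without single replicates (0 without day 15 replicate 2, 35 without day 15 replicate 1), and the lists 0 to 2. The count of 0 against B6 became 1 with the tubular covariate. Without single replicates it was 0 to 1 for early CD19, 0 to 3 for late CD19 and 0 to 1 between the CD19 groups. The correlation of both tables was 0.764 to 0.884 without single replicates.

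With array weights from REML, limma called 62 genes at day 15, 15 in the second table, 80 between days 15 and 17, 41 against B6, 23, 147 and 3 for day 35 against 17, 60 against 35 and 60 against 17, 184 with CD20, 133 with early and 118 with late CD19, and 359 between the CD19 groups. Gene by gene the weights gave 13 at day 15, 37 between days 15 and 17, 56 against B6, 20, 116 and 3 over the later days, 2 with aCD20, 1 with CD20, 78 with early and 79 with late CD19, 326 between the CD19 groups and 19 between aCD20 and CD20. These counts carry little weight, because 12 of 13 REML fits stopped before convergence, and in 20 simulated runs without any change REML weights made calls in 9 (up to 398 genes) and gene-by-gene weights in 10 (up to 328) for the day 15 design, against 0 without weights.

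The replicate block changed no other call, the CD19 groups and aCD20 against CD20, where numbers pair samples, included (0 calls with the block). Where numbers do not pair samples, at day 15 same-number correlations ran from -0.23 to 0.0403, and no sample correlated best with its own number. Of the genes named, the alternatives fixed beforehand left 1290 values on their side of the threshold and within their spread, and 39 moved, 14 gained and 35 lost a call. Low counts limit CCR5/CG replicate 1 of day 15 (144359) and of the second table (169383).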

Other observations

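The hypoxia, oxidative stress and unfolded protein lists and the settings tried on the first, the neighbour test and the splits of the samples were tests chosen only after the results were seen.

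In the second table, several gene lists passed fry's test for change in either direction between CCR5/CG and CCR5 grafts. This test asks whether genes of a list changed and does not require that some rise and others fall. Camera at the estimated correlation, which asks for 1 direction, called 0 lists (smallest adjusted p = 0.445). The chemokine receptor list had adjusted p = 0.00284, and adjusted over the list alone Ccr1 (2.12, SE 0.38) rose while Ccr7 (-1.11, SE 0.24), Cxcr6 (-0.97, SE 0.31) and Cxcr3 (-0.78, SE 0.23) fell, receptors found on T cells. The chemokine list had adjusted p = 0.0115, with Ccl24 (2.76, SE 0.44) higher and Ccl22 (-1.72, SE 0.36) and Xcl1 (-0.96, SE 0.21) lower. In the list of regulatory T cells and checkpoints (adjusted p = 0.00284), Pdcd1lg2 rose (1.13, SE 0.21) and Foxp3, the regulatory T cell factor, had -0.60 (SE 0.31). In the cytotoxic list (adjusted p = 0.0215), Gzma rose (0.72, SE 0.20) and Ctsw fell (-0.60, SE 0.18). Among tubular injury genes (adjusted p = 0.0215), Myc (1.18, SE 0.22), Cdkn1a (1.20, SE 0.33), Lcn2 (1.33, SE 0.42) and Anxa1 (0.68, SE 0.19) rose. Within these lists the genes were adjusted over the list alone, and limma called 0 genes over all 633 tested, with 121 at an unadjusted p under 0.05.

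A hypothesis drawn from Hmox1, Ero1l, Flt1 and Arg1 was that day 15 CCR5/CG grafts may have been short of oxygen. A list of 7 other hypoxia-induced genes was lower in grafts labelled day 17 than in those labelled day 15 (median log2 fold change -0.36, fry adjusted p = 0.00829 over 6 tests), but not past the threshold with camera at the estimated correlation (unadjusted p = 0.115). The day of the latter is in doubt, since they matched samples of the second table labelled days 17, 18 and 19. With each day 15 graft left out in turn, its unadjusted p was 0.000806, 0.00597 and 0.00918. The tubular mean was 2.10 higher at day 17 (exact permutation p = 0.2, and 0.86 higher without day 15 replicate 2), and the median of all genes shifted by -0.14. The list's unadjusted p was 0.000784 with the tubular mean as a covariate (median -0.61), 0.0127 with median scaling (-0.21) and 0.00596 with quantile normalization (-0.17). Against CCR5 grafts at day 15, 6 of the 7 genes were higher, but the list was not past the threshold (median 0.07, adjusted p = 0.165), and its unadjusted p ran from 0.0123 with quantile normalization to 0.191 with camera. The median was 0.30 without CCR5/CG replicate 1, 0.18 without replicate 2 and 0.35 with the tubular covariate. Oxidative stress genes had adjusted p = 0.551 at day 15 and 0.707 between the days, and unfolded protein response genes 0.165 in both. The hypothesis thus stays open for the contrast between genotypes.

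A further hypothesis was that the lower mean of Ccr1 in CCR5/CG than B6 grafts at day 60 could come from a shift of the whole neighbourhood of Ccr5, which lies near Ccr1. Of the 4 other measured genes within 5 Mb by assembly GRCm38.p6, Myd88 and Ctnnb1 are also made by donor cells of the graft, which would hide a shift in recipient cells. The leukocyte genes Ccr2 and Cxcr6 had log2 fold changes of -0.43 (SE 0.43) and -0.15 (SE 0.29), a mean of -0.29, against -1.55 for Ccr1. The 95% intervals of Ccr2 (-1.31 to 0.45) and Cxcr6 (-0.749 to 0.449) lie above -1.55, so for these 2 genes they argue against a shared shift of that size. The interval of Ccr1 itself was -2.50 to -0.60, so a smaller shared shift stays open. A change in Ccr1 alone was not tested further.

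Other splits of the same samples were counted for each comparison. Between days 15 and 17 the real split called 6 genes, 1 of 10 splits gave as many, and the highest other gave 5. For the second table and for day 35 against day 17, the real split and the highest other of 10 called 0 genes. For aCD20 against CD20 the real split of 10 called 0 genes and the highest other 231, which points to a structure of the samples. Among the 4 splits that part all numbered pairs there, the highest other called 0. These designs have too few splits for a share under 0.05. For the other comparisons the real count was 0, so every split gave as many by construction (all 100 drawn, and all 56 between the CD19 groups), and the share says nothing about chance. The same holds for the real counts of 0 among 10 splits. The highest other split called 1 gene against B6, 2 for day 60 against 35, 1 for day 60 against 17, 1 with aCD20, 2 with CD20, 1 with early CD19, 0 with late CD19 and 2 between the CD19 groups.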
